A study of Bos taurus with 12 samples.

How the data were processed

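Endometrium of 12 ovariectomized cows was measured with 1 Affymetrix bovine array per cow, in 4 groups of 3 cows: control, estrogen, progesterone, and progesterone followed by estrogen. Group, dose and days of treatment were taken from the sample labels. The values deposited by the authors are log2 signals, summarised from the probe intensities with RMA (robust multi-array average, which corrects background, normalizes across arrays by quantiles and takes log2) per the submitters' processing notes. The version of RMA is not given in the sources used here, and the array images were not reprocessed. No further transformation was applied, and no pseudocount was needed. The number of arrays, 3 per group with 8 residual degrees of freedom, limited the precision, and an array has no sequencing depth.

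The deposited table held 24128 probe sets with 0 missing values, and all 12 columns were used. The 112 Affymetrix control probe sets were left out, which left 24016. The array annotation listed 1 gene for 13296 probe sets, several for 82 and none for 10638. Those with 1 gene were matched by Entrez ID to a RefSeq gene table (13283 matched, 0 symbols updated), and 13103 carried a symbol that is not a LOC number, 9032 different symbols in all. Probe sets without a gene were tested and counted but not named. MKI67 and HAND2 had no annotated probe set.

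A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances. The 7 comparisons were the estrogen, progesterone and combined groups against control, the combined group against progesterone and against estrogen, progesterone against estrogen, and the interaction, which is the combined minus progesterone difference less the estrogen minus control difference. The p-values of limma are two-sided, measure the spread between cows, and were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as threshold. Samples, comparisons, gene lists and most alternatives were fixed before the data were examined. Genes were named from the largest changes in each direction with an adjusted p under 0.05 whose arrays did not overlap between the groups compared, a condition not used for the interaction. Where fewer than 5 genes passed in a direction, those of smallest p were taken, and hormone-related genes fixed beforehand were given against control whatever their result. Where a gene named by these rules had several probe sets, the others were looked at. Other list members, and the genes under other observations, were read only from the probe set of highest mean.

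There were 24 gene lists and 15 cell type lists, written from general knowledge. Of these, 38 had at least 4 measured genes and were tested among 9159 genes, with the probe set of highest mean per gene. Lists were tested with camera of limma at a preset correlation between genes of 0.01, with camera at a correlation estimated from the arrays, and with fry. Adjustment was by Benjamini-Hochberg over the lists of a comparison. Members were counted at the adjusted p over all probe sets, and again with adjustment over the list alone. Lists that camera called are described, and so are lists with at least 5 passing members in the comparisons with control; between the hormone groups, of the latter only prostaglandin and oxytocin signalling is given, with cell type markers beside it. The level of a list in an array was the mean of its members relative to the control mean.

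Responses were compared by correlation and covariance of log2 changes across probe sets. Groups without a difference were simulated against shared controls 100 times. Overlaps of called probe sets were set beside the number from independent lists.

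Alternatives were quantile normalization, array medians subtracted, probe sets with all group means under the 40th percentile left out, array weights, a trend with robust variances, replicate number as a block, only the arrays compared, each array left out in turn, a change of at least 2-fold, 1 probe set per gene, and adjustment over all 7 comparisons. Lists were also tested on the mean of a gene's probe sets. Leaving out both arrays of lowest weight was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

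The procedure was tested on simulated data with the spread of these arrays, in which 100 probe sets were changed by 1 and 100 by 2 on the log2 scale. In the estrogen comparison 69% and 96% of these were recovered with 7 false calls, in the progesterone comparison 72% and 93% with 10, and in the combined group against control 76% and 96% with 6. The combined group against progesterone gave 71% and 96% with 10, the combined group against estrogen 72% and 98% with 9, progesterone against estrogen 72% and 91% with 5, and the interaction 50% and 83% with 8. A shifted list was found in each of the 7 comparisons, and 1 other list was called, in progesterone against estrogen. The simulated probe sets were drawn independently of each other. The simulation therefore cannot show how often camera calls lists falsely when genes are correlated. Without any change limma made 0 calls in each comparison.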

Results

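Endometrium, the inner lining of the uterus, was profiled in 12 ovariectomized cows divided at random into 4 groups of 3, with 1 Affymetrix bovine expression array per cow. Ovariectomy removes the main source of the cow's own estrogen and progesterone, so that the hormones given were the ones compared. Control cows received saline on day 0. Estrogen cows received saline on day 0 and 1 mg of estradiol benzoate, a long-acting estradiol ester, on day 5. Progesterone cows carried 2 progesterone-releasing devices from day 0 to day 6. Cows of the combined group carried 2 such devices from day 0 and received 1 mg of estradiol benzoate directly after the devices were taken out on day 6. Tissue was taken at slaughter, 2 days after a blood sample. The blood sample was drawn on day 5 in the control and progesterone groups, which puts slaughter on day 7, 1 day after device removal in the progesterone group. In the groups given estradiol benzoate the blood sample followed that injection, on a day not given in the sources used here. Any comparison of a group given estradiol benzoate with a group not given it may therefore join hormone and sampling day, and the combined group also had more time after device removal than the progesterone group. The estrogen and combined groups, injected on day 5 and day 6, may also differ in sampling day or in time after injection. Values are log2 signals of 24016 probe sets, sets of short probes designed to read a transcript, and the precision was limited by the number of arrays. The median standard error (SE) of a log2 difference between a pair of groups was 0.148.

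The arrays separated by treatment with estradiol benzoate. The correlation of arrays across probe sets, which are not independent replicates, ran from 0.939 to 0.994. The mean correlation within a group was 0.993 for estrogen, 0.986 for control, 0.981 for progesterone and 0.978 for the combined group, and the combined arrays correlated with the estrogen arrays at 0.981 on average. The first principal component held 40.8% of the variance. It placed the 6 arrays with estradiol benzoate between 30.0 and 51.0 and the 6 arrays without it between -60.9 and -23.3. Each combined array correlated at least as closely with the estrogen arrays as with its own group, at 0.989 against 0.979 for replicate 1, 0.9763 against 0.9758 for replicate 2 and 0.97835 against 0.97808 for replicate 3. Epithelium and smooth muscle markers varied within the combined group. Relative to the control mean, the mean level of 19 epithelium markers was -0.32, -0.79 and -1.51 in its replicates, and that of 13 smooth muscle markers was 0.13, 2.84 and 1.10. Markers of the milk-secreting mammary epithelium, measured because the extraction wording in the labels names mammary gland tissue, had a median change of -0.04 in the estrogen group, -0.14 in the progesterone group and 0.12 in the combined group. A change between groups cannot tell which tissue was sampled, so these values do not settle that wording.

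**Figure D1:**
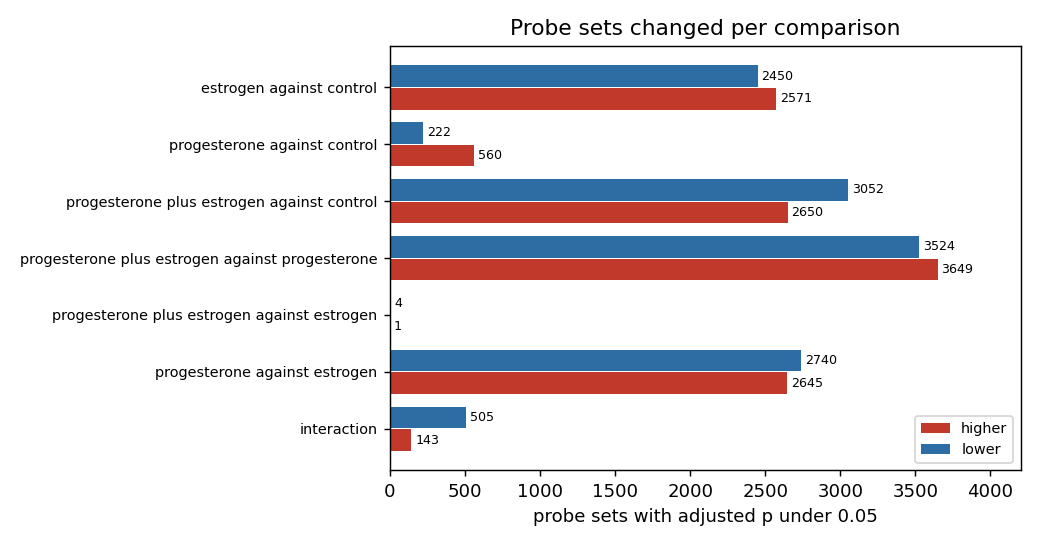
The bars give the number of probe sets called higher (red) and lower (blue) on the x axis, in each of the 7 comparisons on the y axis, by limma at a Benjamini-Hochberg adjusted p under 0.05, out of 24016 tested. The combined group differed from the estrogen group in 5 probe sets and from the progesterone group in 7173. The former count was 320 without combined replicate 1 and 888 with adjustment over all 7 comparisons. That adjustment does not hold the 0.05 rate within a single comparison.

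Estradiol benzoate alone changed genes of matrix, sterol synthesis and protein folding. TAC3, the precursor of the tachykinin neurokinin B, rose by 4.37 on the log2 scale (SE 0.39, n = 3 per group, adjusted p = 0.000247), a 20.7-fold difference. That fold rests on a low control signal of 4.50, 5.01 and 5.35, below the 25th percentile of the control arrays (5.61 to 5.62). The extracellular glutathione peroxidase GPX3 rose by 4.19 (SE 0.56), monoamine oxidase B (MAOB) by 3.82 (SE 0.28) and INHBA, the activin subunit, by 3.26 (SE 0.27). The WNT enhancer RSPO3 rose by 3.18 (SE 0.53), and CCNB1, the mitotic cyclin B1, by 3.03 (SE 0.49). The CCNB1 rise was not particular to estradiol benzoate. Its values were 7.78, 8.30 and 9.47 in the progesterone arrays, against 5.74, 5.12 and 5.84 in controls. SCARA5, a ferritin receptor, fell by 3.53 (SE 0.49, adjusted p = 0.00108), ADAMDEC1 by 3.56 (SE 0.76), the pantetheinase VNN1 by 3.13 (SE 0.58) and SELENBP1 by 2.66 (SE 0.34). Of 34 genes of the unfolded protein response and folding in the endoplasmic reticulum, 22 rose and 0 fell, with 25 higher when adjusted over the list alone. CRELD2 (1.91, SE 0.17), KDELR3 (1.82, SE 0.16) and the disulfide isomerase P4HB (0.82, SE 0.10) were among them. Of 17 cholesterol synthesis genes, 13 rose and 0 fell (14 higher adjusted over the list alone), including INSIG1 (1.83, SE 0.30), ACAT2 (1.49, SE 0.22) and LSS (1.39, SE 0.19). Of 37 genes of collagens and fibrillar matrix, 19 rose and 1 fell (22 and 2 adjusted over the list alone). PCOLCE rose by 2.46 (SE 0.25) and the collagen chaperone SERPINH1 by 2.08 (SE 0.18). In the same arrays the mean level above control was 0.29 for 15 fibroblast stroma markers (4 higher and 1 lower, with 6 and 1 adjusted over the list alone). It was 0.45 for 13 smooth muscle markers. The fibroblast stroma median was 0.09, and that list shares PCOLCE, COL1A1 and other genes with the matrix list. Of 44 oxidative phosphorylation genes, 18 rose and 1 fell (31 and 1 adjusted over the list alone), with COX7A2 at 0.85 (SE 0.13) and NDUFS1 at 0.60 (SE 0.09). Among 18 T and NK lymphocyte markers, 2 fell (1 adjusted over the list alone), CD247 by 1.33 (SE 0.27) and GZMB by 1.08 (SE 0.32). Of 16 markers of macrophages and dendritic cells, MS4A7 fell by 0.67 (SE 0.16) and 15 did not pass (1 lower adjusted over the list alone). These 6 lists were called by camera with a preset correlation (adjusted p from 9.17e-09 to 0.0407), and each had adjusted p = 0.843 with an estimated correlation. Without control replicate 3 the T and NK lymphocyte median was -0.52 (adjusted p = 0.233, in a range from 0.000797) and the macrophage and dendritic cell median -0.19 (0.380, in a range from 0.00709). The latter call was also lost without estrogen replicate 1 (0.0730) and progesterone replicate 2 (0.0506).

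In the same comparison, limma called 5021 of 24016 probe sets, 2571 higher and 2450 lower, of which 551 and 501 differed at least 2-fold. Without control replicate 2 the count was 3333, and without estrogen replicate 1 it was 3174. The lists of matrix proteases and inhibitors (8 higher, 3 lower of 33; also 8 and 3 adjusted over the list alone) and of the transforming growth factor beta family (6 higher, 2 lower of 28; 6 and 3 adjusted over the list alone) were not called by camera. TGFB3 in the latter rose by 2.86 (SE 0.41), and ADAMTS4 in the former by 2.20 (SE 0.30). Of 35 genes of DNA replication, 8 rose and 6 fell (11 and 6 adjusted over the list alone), with UHRF1 at 2.11 (SE 0.42) and CDC45 at -0.72 (SE 0.12); the median of this list was -0.03, its mean 0.13 and the direction of its test down, and the median turned positive with array medians subtracted. Other lists not called had 5 of 35 higher and 0 lower for fatty acid and glucose metabolism (2 and 0 adjusted over the list alone), with SCD at 2.77 (SE 0.34), and 5 of 23 higher for heat shock proteins (6 and 0). Solute carriers had 6 of 29 higher and 1 lower (7 and 3), the IGF system 4 of 16 and 1 (4 and 1), and angiogenesis 4 of 32 and 2 (5 and 4), with its median and mean above 0 and its test down. Cell adhesion had 1 of 34 higher and 5 lower (1 and 5), and the textbook progesterone list 1 of 33 higher and 4 lower (1 and 2). DAPL1 (3.15, SE 0.85), CLDN11 (-2.73, SE 0.70) and GSTA2 (-2.60, SE 0.68) lost their calls without some arrays. Their highest adjusted p was 0.0905 for DAPL1 without estrogen replicate 2, 0.0752 for CLDN11 without control replicate 2 and 0.0791 for GSTA2 without control replicate 1, and their lowest was 0.00651, 0.00691 and 0.00887.

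**Figure D2:**
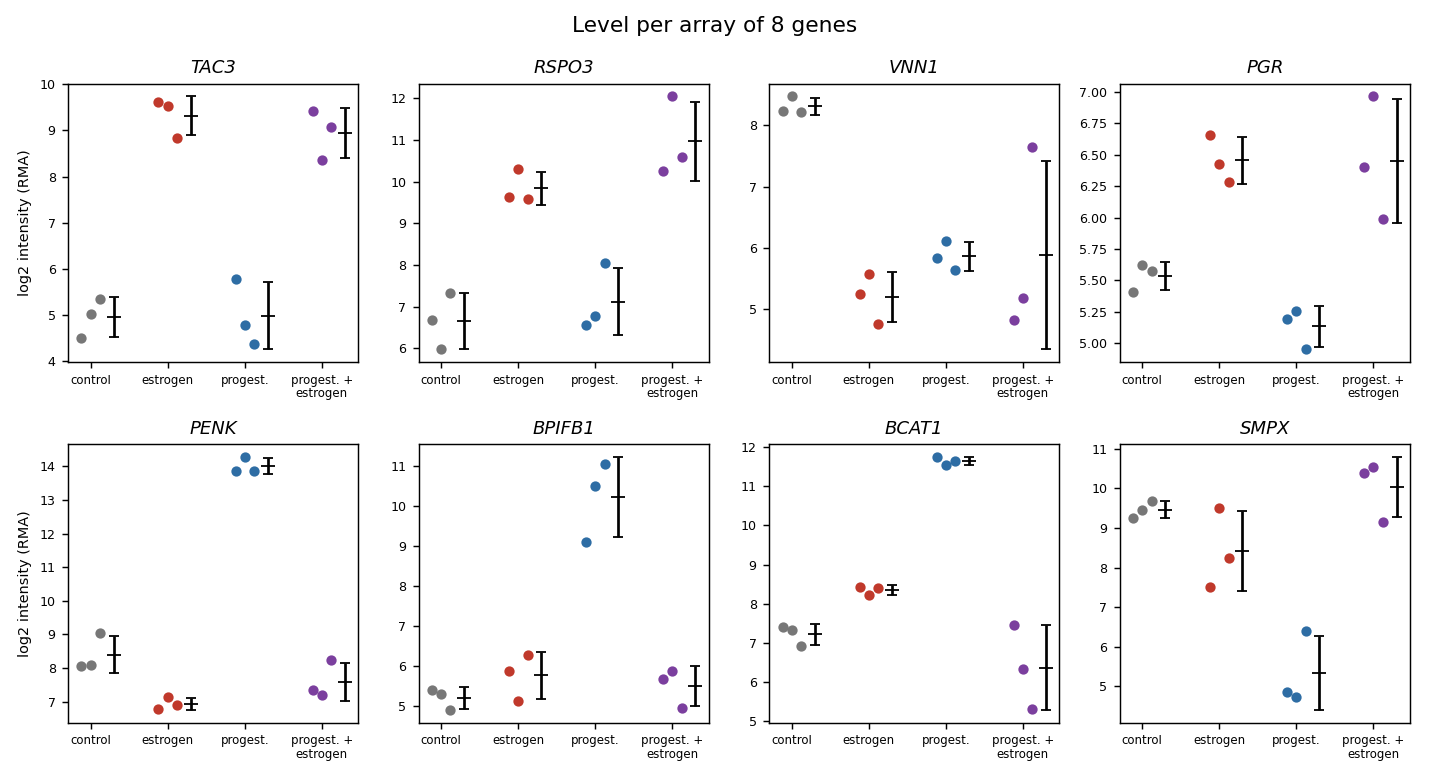
Log2 signal (y axis) of 8 genes in each of the 12 arrays by group (x axis). Points are arrays, and bars give the group mean with its standard deviation, n = 3 per group. TAC3 averaged 9.32 in the estrogen group and 8.95 in the combined group against 4.95 in controls, and PENK averaged 14.00 in the progesterone group against 8.40 in controls and 7.59 in the combined group.

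Progesterone alone changed fewer probe sets but gave the largest rises of single genes. PENK, the enkephalin precursor, rose from a mean of 8.40 to 14.00, by 5.60 on the log2 scale (SE 0.31, n = 3 per group, adjusted p = 1.47e-05), a 48.7-fold difference. BPIFB1, a secreted protein of mucosal surfaces, rose by 5.03 (SE 0.46), the zinc transporter SLC39A2 by 4.63 (SE 0.29), the metalloprotease MEP1B by 4.57 (SE 0.37) and the oxysterol hydroxylase CYP39A1 by 4.47 (SE 0.23). BCAT1, the cytosolic branched-chain aminotransferase, rose by 4.43 (SE 0.40) and the sodium-glucose cotransporter SLC5A1 by 4.34 (SE 0.38). CRIPTO rose by 4.46 (SE 0.65), SMPDL3B by 4.29 (SE 0.60) and CHGA, chromogranin A, by 4.48 (SE 0.57), while the means of a second CHGA probe set were 10.88 in controls and 11.62 in the progesterone group. The control signals of BPIFB1, MEP1B, CRIPTO and SMPDL3B all lay below the 25th percentile of the control arrays (5.61 to 5.62). Their sizes therefore rest on low control signals. The muscle protein gene SMPX fell by 4.14 (SE 0.57, adjusted p = 0.00377), the uroplakin UPK1B by 3.47 (SE 0.35), SCNN1G, the gamma subunit of the epithelial sodium channel, by 2.59 (SE 0.39), CLDN10 by 2.57 (SE 0.37) and CYP4B1 by 1.99 (SE 0.19). Of 33 genes taken from textbooks as progesterone responses of endometrium, 4 rose and 1 fell (10 and 4 adjusted over the list alone). These were SLC5A1, IGFBP1 (3.75, SE 0.74), CST6 (2.90, SE 0.48) and FST (1.92, SE 0.32) on the higher side and IGFBP3 (-2.34, SE 0.41) on the lower; the list median was -0.03 while the direction of its test was up, and it was not called (adjusted p = 0.343). Of 17 cholesterol synthesis genes, 5 rose and 0 fell (14 higher adjusted over the list alone), among them INSIG1 (1.46, SE 0.30), MSMO1 (1.23, SE 0.19) and FDFT1 (1.21, SE 0.23). Of 35 genes of fatty acid and glucose metabolism, 5 rose and 0 fell (8 and 2 adjusted over the list alone), with the glucose transporter SLC2A1 at 2.12 (SE 0.22) and the acetyl-CoA carboxylase ACACA at 1.02 (SE 0.18). Of 29 solute carriers and channels, 4 rose and 2 fell (8 and 4 adjusted over the list alone), SLC1A1 by 3.19 (SE 0.36) on the higher side.

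Camera with a preset correlation called 6 lists in this comparison, and none of the 6 was called with an estimated correlation. Cholesterol synthesis (adjusted p = 2.51e-08) and oxidative phosphorylation (1.48e-06; 2 of 44 members higher, 4 adjusted over the list alone) were called up. Cytosolic ribosomal proteins (6.46e-06; 0 of 50 passing) and endothelium (0.00507; 0 of 14 passing) were called down. All 4 had adjusted p = 0.864 with an estimated correlation. Fatty acid and glucose metabolism (0.00645, up) had adjusted p = 0.610 with an estimated correlation, and macrophages and dendritic cells (0.0322, down; 0 of 16 passing) had 0.871. The macrophage median was -0.14 without control replicate 3 (adjusted p = 0.447) and -0.22 without progesterone replicate 1 (0.266), with 0.00116 as the lowest value over the arrays left out. Adjusted over the list alone, 0 members of the ribosomal, endothelium and macrophage lists passed; limma called 4736 probe sets of the whole array at an unadjusted p under 0.05. In all, limma called 782 probe sets, 560 higher and 222 lower. The count was 438, 303 and 466 without control replicates 1, 2 and 3, 1194 without progesterone replicate 1 (661 higher and 533 lower) and 413 without progesterone replicate 3. VNN1 (-2.45, SE 0.58), HERC5 (-2.09, SE 0.46), GPC3 (-2.07, SE 0.47) and IGFBP3 lost their calls without 9, 7, 7 and 2 of the 12 arrays. Their adjusted p then ran up to 0.153 (VNN1, without control replicate 2), 0.126 (HERC5, without progesterone replicate 3), 0.104 (GPC3, without progesterone replicate 2) and 0.0605 (IGFBP3, without control replicate 2), from lowest values of 0.000407, 0.000772, 0.0264 and 0.00390.

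Progesterone followed by estradiol benzoate raised many of the genes that estradiol benzoate alone had raised most. RSPO3 rose by 4.31 on the log2 scale against control (SE 0.53, n = 3 per group, adjusted p = 0.000878), GPX3 by 3.67 (SE 0.56), the lectin gene REG4 by 3.63 (SE 0.70), MAOB by 3.55 (SE 0.28) and CCNB1 by 3.24 (SE 0.49). CCNB1 was also higher in each array with progesterone alone than in any control array. TAC3 rose from a mean of 4.95 to 8.95 (SE of the difference 0.39). HSD17B13 fell by 4.01 (SE 0.83, adjusted p = 0.00766), the granzyme gene gzmA by 3.53 (SE 0.73), the D-aspartate oxidase DDO by 3.30 (SE 0.41), UPK1B by 2.85 (SE 0.35) and the kallikrein KLK10 by 2.66 (SE 0.37). Of 26 mitosis genes, 19 rose and 0 fell (20 higher adjusted over the list alone), among them KIF20A (1.36, SE 0.18), CDCA3 (1.24, SE 0.21) and KIF2C (1.11, SE 0.17). Of 37 genes of collagens and fibrillar matrix, 20 rose and 1 fell (23 and 1 adjusted over the list alone), with OGN at 3.13 (SE 0.43), ASPN at 2.78 (SE 0.34) and SERPINH1 at 1.62 (SE 0.18). The 15 fibroblast stroma markers, some of them also in the matrix list, stood at a mean of 0.38 and a median of 0.28 above control. Of these, 3 were higher and 1 lower (4 and 1 adjusted over the list alone), and camera did not call the list. Matrix proteases and inhibitors had 12 of 33 higher and 2 lower (14 and 2 adjusted over the list alone), with ADAMTS4 at 1.87 (SE 0.30) and MMP19 at 1.48 (SE 0.23). Oxidative phosphorylation had 18 of 44 higher and 0 lower (23 and 1 adjusted over the list alone), the unfolded protein response 10 of 34 higher and 2 lower (12 and 3), and cholesterol synthesis 4 of 17 higher and 0 lower (7 and 0). Of 19 epithelium markers, 0 rose and 9 fell (12 lower adjusted over the list alone), CLDN3 by 1.92 (SE 0.29), the cadherin CDH1 by 1.77 (SE 0.35) and RAB25 by 1.66 (SE 0.26). Of 13 smooth muscle markers, 5 rose (also 5 adjusted over the list alone), with ACTA2 at 1.66 (SE 0.36); in each array this list stood at 0.13, 2.84 and 1.10 above the control mean, and the epithelium list at -0.32, -0.79 and -1.51.

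Members of 4 further lists were lower in the combined group than in controls. Of 20 immediate early genes, 9 fell and 0 rose (10 and 1 adjusted over the list alone), DUSP1 by 1.25 (SE 0.19) and JUN by 0.95 (SE 0.17). Of 21 antigen presentation genes, 9 fell (11 lower and 1 higher adjusted over the list alone), B2M by 0.67 (SE 0.13) and BOLA-DMA by 1.25 (SE 0.29). Markers of cells that present antigen had medians of -0.44 for macrophages and dendritic cells (0 of 16 higher and 3 lower; 0 and 1 adjusted over the list alone) and -0.93 for B and plasma cells (0 of 9 and 1; 0 and 1), and camera called neither. Of 28 interferon-stimulated genes, 7 fell (9 adjusted over the list alone), IRF9 by 0.85 (SE 0.18) and DTX3L by 0.81 (SE 0.14). Of 18 T and NK lymphocyte markers, 6 fell (11 lower and 1 higher adjusted over the list alone), the perforin gene PRF1 by 1.61 (SE 0.36) and CD247 by 1.39 (SE 0.27). The cell adhesion list, which shares CLDN3 with the epithelium list, had 11 of 34 lower and 2 higher (13 and 3 adjusted over the list alone), with the junction gene CGN down by 2.05 (SE 0.31); camera did not call it (adjusted p = 0.0795). Camera with a preset correlation called 12 lists, the others described so far for this comparison except fibroblast stroma, macrophages and dendritic cells, and B and plasma cells, with adjusted p from 6.92e-07 for mitosis to 0.0435 for the unfolded protein response, and all 12 had adjusted p = 0.919 with an estimated correlation. Without control replicate 3, in which the immediate early, interferon-stimulated and T and NK lymphocyte levels lay above those of the other controls, the calls of these lists (0.0578, 0.0783 and 0.0783) and of cholesterol synthesis (0.0578) were lost. Without combined replicate 2 the smooth muscle median was 0.65 (0.0670), that of cholesterol synthesis 0.28 (0.163), that of interferon-stimulated genes -0.24 (0.0872) and that of the unfolded protein response 0.22 (0.0697). The unfolded protein response also lost its call without control replicate 1 (0.0774), progesterone replicates 2 (0.0552) and 3 (0.0509) and combined replicate 1 (0.177), and matrix proteases without combined replicate 3 (0.0608). The lowest values over the arrays left out were 0.000131, 0.00369, 0.000974, 0.000362, 1.04e-05, 0.0128 and 0.00127 for immediate early genes, interferon-stimulated genes, T and NK lymphocytes, cholesterol synthesis, smooth muscle, the unfolded protein response and matrix proteases. Lists not called included DNA replication with 11 of 35 higher and 2 lower (12 and 4 adjusted over the list alone), the IGF system with 5 of 16 and 1 (5 and 1), and solute carriers with 5 of 29 and 2 (5 and 2). Endothelium had a median of -0.32 with 2 of 14 higher and 5 lower (3 and 5), and was called without combined replicate 3 (-0.58, 0.0234) but not without replicate 2 (-0.08, 0.669). The textbook estrogen list had 4 of 24 and 3 (6 and 5), the textbook progesterone list 2 of 33 and 4 (2 and 4), and antimicrobial genes 1 of 36 and 4 (0 and 2). Angiogenesis had 4 of 32 in each direction (4 and 4) and the transforming growth factor beta family 4 of 28 and 3 (4 and 3). The median of the solute carrier, angiogenesis and textbook progesterone lists was above 0 while their tests pointed down. Limma called 5702 probe sets, 2650 higher and 3052 lower; with array medians subtracted the split was 3527 higher and 2560 lower. Without control replicate 1 the count was 3733 and without control replicate 2 it was 3709. MMP3 (3.23, SE 0.97), DAPL1 (3.24, SE 0.85), ADAMDEC1 (-2.95, SE 0.76), EFEMP1 (-2.37, SE 0.72) and PIGR (-2.35, SE 0.74) lost their calls without some arrays, with adjusted p up to 0.108 (MMP3, without combined replicate 1), 0.0729 (DAPL1, without control replicate 2), 0.0614 (ADAMDEC1, without combined replicate 2), 0.117 (EFEMP1, without control replicate 1) and 0.0974 (PIGR, without combined replicate 2). The lowest values were 0.00395, 0.0104, 0.00564, 0.0193 and 0.0371. EFEMP1 had -1.34 without combined replicate 1 (0.0501) and PIGR -1.34 without control replicate 3 (0.0876). The epithelium median, -0.93, was -0.49 without combined replicate 3 (0.00272).

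**Figure D3:**
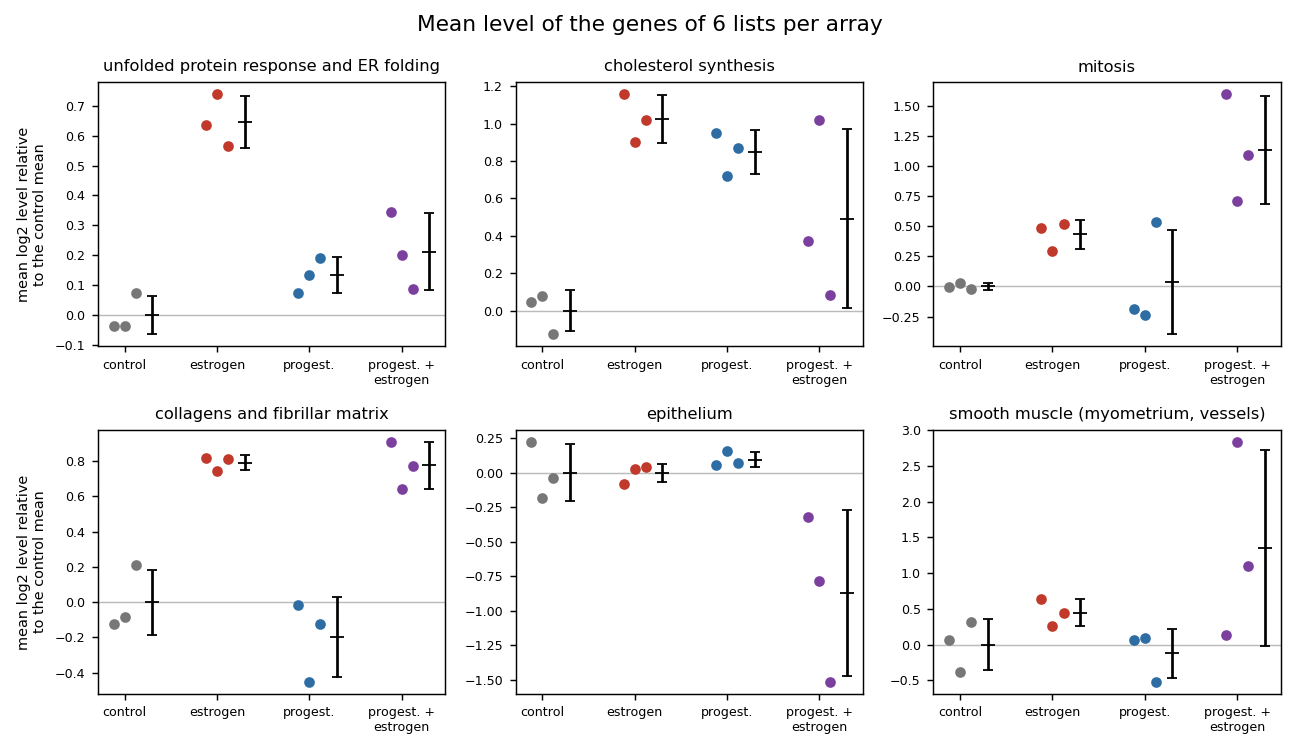
Mean log2 level of the genes of 6 lists relative to the control mean (y axis) in each of the 12 arrays by group (x axis). Points are arrays, and bars give the group mean with its standard deviation, n = 3 per group. The epithelium level was -0.32, -0.79 and -1.51 and the smooth muscle level 0.13, 2.84 and 1.10 in the arrays of the combined group.

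The combined group and the progesterone group, which also differed in sampling day, were set beside each other next. SMPX was higher in the combined group by 4.70 on the log2 scale (SE 0.57, n = 3 per group, adjusted p = 0.000435), the chemokine CXCL14 by 4.42 (SE 0.66), GPX3 by 4.18 (SE 0.56), the matrix glycoprotein tenascin C (TNC) by 4.14 (SE 0.44) and MAOB by 3.99 (SE 0.28). The second TNC probe set had means of 6.02 in the progesterone group and 6.26 in the combined group. PENK was lower, with a difference of -6.41 (SE 0.31, adjusted p = 5.60e-06), followed by SLC5A1 (-5.29, SE 0.38), BCAT1 (-5.28, SE 0.40), MEP1B (-5.24, SE 0.37) and SLC39A2 (-4.91, SE 0.29). In the list of prostaglandin and oxytocin signalling, 3 of 19 were higher and 4 lower (3 and 5 adjusted over the list alone). The inducible cyclooxygenase PTGS2 (-4.78, SE 0.47), the prostaglandin dehydrogenase HPGD (-3.87, SE 0.55) and the aldo-keto reductase AKR1C4 (-3.79, SE 0.35) were lower and the receptor PTGER4 (1.85, SE 0.25) higher. AKR1C4 was read only from the brightest of its 6 probe sets. Of 37 collagen and matrix genes, 24 were higher and 1 lower (27 and 1 adjusted over the list alone), with ASPN at 3.33 (SE 0.34), and of 26 mitosis genes 19 were higher (21 adjusted over the list alone), with AURKB at 1.17 (SE 0.18). Of 28 interferon-stimulated genes, 13 were lower and 1 higher (14 and 1 adjusted over the list alone), with GBP4 at -2.65 (SE 0.49). The 15 fibroblast stroma markers had a median of 0.58 (6 higher and 1 lower; 7 and 1 adjusted over the list alone) and the 18 T and NK lymphocyte markers -0.85 (1 and 2; 0 and 0). Camera called neither, but without combined replicate 2 it called fibroblast stroma (median 0.63, adjusted p = 0.0415), and without that array the smooth muscle median was 0.71 (0.0312). Of 19 epithelium markers, 13 were lower and 2 higher (13 and 2 adjusted over the list alone), with CLDN4 at -2.76 (SE 0.34) and CLDN10 at 3.44 (SE 0.37); smooth muscle markers had 5 of 13 higher (6 adjusted over the list alone). Immediate early genes had 8 of 20 lower and 1 higher (8 and 1 adjusted over the list alone), antigen presentation 5 of 21 lower (3), ribosomal proteins 13 of 50 higher (10) and ciliated epithelium 3 of 6 lower (4). Markers of cells that present antigen had medians of -0.80 for B and plasma cells and -0.12 for macrophages and dendritic cells. Camera did not call these cell type lists, nor prostaglandin and oxytocin signalling, fibroblast stroma and T and NK lymphocytes. It called the other lists of this paragraph, 9 in number, with adjusted p from 2.84e-07 for collagens to 0.0341 for ciliated epithelium. Each of the 9 had adjusted p = 0.772 with an estimated correlation. The antigen presentation call was lost without progesterone replicate 3 (0.0867), and the ciliated epithelium call without progesterone replicate 2 (median -0.82, 0.110) and combined replicate 3 (0.0729), with 0.00848 and 0.0157 as the lowest values. Limma called 7173 probe sets, 3649 higher and 3524 lower, with 4479 and 3147 after array medians were subtracted and 1144 and 1629 with only the arrays compared. The count was 4146 without both arrays of lowest quality weight, progesterone replicate 3 and combined replicate 2, a setting chosen after the data were seen.

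Between estradiol benzoate with and without earlier progesterone, few single probe sets passed the adjusted threshold. Injection was on day 6 with earlier progesterone and on day 5 without it, so sampling day or time after injection may differ as well. Limma called 5 of 24016, 1 higher and 4 lower (1 and 2 with array medians subtracted), and 888 with adjustment over all 7 comparisons. An unadjusted p under 0.05 was reached by 3454, where 1201 would be expected without any difference. TCP11L2 was higher in the combined group by 1.23 (SE 0.15, n = 3 per group, adjusted p = 0.0437). The glycosyltransferase gene MGAT5B (-1.50, SE 0.16, adjusted p = 0.0394), the matrix Gla protein MGP (-1.63, SE 0.19, 0.0437; 2 probe sets) and GMPPB (-1.10, SE 0.14, 0.0499) were lower. The probe sets of MGP disagreed, since its brightest had a mean of 12.52 in the estrogen group and 13.08 in the combined group, and another MGAT5B probe set had means of 6.08 and 6.04. Values just past the threshold were UPK1B at -2.53 (SE 0.35), HYOU1, a chaperone of the endoplasmic reticulum, at -0.98 (SE 0.13) and SPARCL1 at 0.96 (SE 0.13), each with adjusted p = 0.0578. The call was lost without 10 arrays for TCP11L2, 8 for MGAT5B, 9 for MGP and 11 for GMPPB of the 12, with adjusted p up to 0.232, 0.178, 0.232 and 0.247 and down to 0.0154, 0.00724, 0.000677 and 0.0154. The count of calls was 320 without combined replicate 1 (120 higher and 200 lower). It was 3 without control replicate 1, 1 without estrogen replicate 3, and 0 without control replicate 2, estrogen replicate 1 or 2, any progesterone replicate, or combined replicate 2 or 3, with 2297 to 3833 probe sets at an unadjusted p under 0.05 in those fits. Several gene lists had medians away from 0 with 0 single members passing over all probe sets. The medians were -0.37 for 34 genes of the unfolded protein response (0 higher and 21 lower adjusted over the list alone), -0.52 for 17 cholesterol synthesis genes (0 and 3), 0.75 for 26 mitosis genes (12 and 0), -0.95 for 19 epithelium markers (0 and 14) and 0.80 for 13 smooth muscle markers (0 and 0). KIF20A in the mitosis list stood at 0.89 (SE 0.18, adjusted p = 0.10 over all probe sets). Camera with a preset correlation called these and the lists of DNA replication (median 0.19), heat shock proteins (-0.18), immediate early genes (-0.52) and ribosomal proteins (0.06), with adjusted p from 2.70e-13 to 0.0109. With an estimated correlation the adjusted p was 0.676 for the unfolded protein response and 0.758 for the others. Without combined replicate 2 the smooth muscle median was 0.15 (adjusted p = 0.278) and that of heat shock proteins -0.33 (1.15e-06), and without combined replicate 1 the smooth muscle median was 1.32. Without combined replicate 3 the medians were -0.46 for epithelium (4.30e-06) and -0.30 for cholesterol synthesis (0.00936). Without combined replicate 1 the medians were 0.07 for DNA replication (0.241), -0.15 for heat shock proteins (0.156) and -0.46 for immediate early genes (0.0700). Heat shock proteins also lost their call without combined replicate 3 (-0.10, 0.242) and ribosomal proteins without estrogen replicate 3 (0.03, 0.144). The lowest values were 2.76e-08 for smooth muscle, 4.79e-06 for DNA replication, 1.15e-06 for heat shock, 0.000987 for immediate early and 0.000129 for ribosomal genes.

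Progesterone alone was also compared with estradiol benzoate alone, where the sampling day of the estrogen group is not given in the sources used here. PENK was higher with progesterone by 7.07 (SE 0.31, n = 3 per group, adjusted p = 4.00e-06), MEP1B by 5.50 (SE 0.37), SLC5A1 by 5.32 (SE 0.38), SCARA5 by 5.04 (SE 0.49) and SLC39A2 by 4.81 (SE 0.29). GPX3 (-4.71, SE 0.56), TAC3 (-4.34, SE 0.39), MAOB (-4.25, SE 0.28), TNC (-3.87, SE 0.44) and the UDP-glucose receptor P2RY14 (-3.83, SE 0.35) were lower with progesterone. Of the prostaglandin and oxytocin signalling genes, 4 of 19 were higher and 3 lower (5 and 4 adjusted over the list alone), with AKR1C4 at 4.72 (SE 0.35), PTGS2 at 4.59 (SE 0.47) and HPGD at 3.48 (SE 0.55). Of 37 collagen and matrix genes, 0 were higher and 21 lower (1 and 25 adjusted over the list alone), with SERPINH1 at -2.46 (SE 0.18) and COL5A2 at -2.15 (SE 0.18). The unfolded protein response had 0 of 34 higher and 21 lower (2 and 21 adjusted over the list alone), with HYOU1 at -1.20 (SE 0.13). Of 28 interferon-stimulated genes, 9 were higher and 0 lower (10 and 0 adjusted over the list alone), with ISG15 at 1.28 (SE 0.32). Cell type lists that camera did not call had medians of -0.38 for fibroblast stroma (2 of 15 higher and 5 lower; 2 and 7 adjusted over the list alone), -0.50 for smooth muscle (0 of 13 and 1; 0 and 0), 0.51 for T and NK lymphocytes (0 of 18 passing; 0 and 0) and 0.99 for B and plasma cells (0 of 9; 0 and 0). At an unadjusted p under 0.05 limma called 8530 probe sets of the whole array. Camera called these 3 lists, matrix, unfolded protein response and interferon-stimulated genes, with adjusted p of 2.74e-07, 5.85e-06 and 0.000813, and all had adjusted p = 0.921 with an estimated correlation. Limma called 5385 probe sets, 2645 higher and 2740 lower, and 3396 without estrogen replicate 1.

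The interaction asked whether the effects of the hormones added up on the log2 scale, as the change with estradiol benzoate after progesterone minus the change without it. Many of the largest negative terms were of genes raised by progesterone alone but not to a like extent in the combined group. PENK stood at 13.85, 14.28 and 13.88 in the progesterone arrays and at 7.35, 7.20 and 8.24 in the combined arrays. BCAT1 stood at 11.75, 11.54 and 11.64 against 7.46, 6.33 and 5.30. A rise kept in full after estradiol benzoate would give a term near 0. Since the term subtracts the progesterone difference, error in that difference also enters it. BCAT1 had -6.41 (SE 0.57, n = 3 per group, adjusted p = 0.000548), BPIFB1 -5.29 (SE 0.65), CYP39A1 -5.07 (SE 0.32), PENK -4.95 (SE 0.43), SLC39A2 -4.73 (SE 0.41), the carboxypeptidase gene CPN1 -4.56 (SE 0.39), MEP1B -4.31 (SE 0.52), SLC5A1 -4.30 (SE 0.53) and PTGS2 -4.27 (SE 0.67). These 9 kept an adjusted p under 0.05 without each of the 12 arrays in turn. SMPX had the largest positive term, 5.75 (SE 0.80, adjusted p = 0.00765). This gene was lower with progesterone (4.85, 4.73 and 6.41 in its arrays) but not in the combined group (10.40, 10.54 and 9.15). FOXP2 (2.58, SE 0.43), TRAF5 (1.93, SE 0.34) and KCNJ8 (1.79, SE 0.31) were also positive, with adjusted p up to 0.0523 without estrogen replicate 2, 0.0643 without estrogen replicate 2 and 0.0547 without control replicate 2, from lowest values of 0.0154, 0.00333 and 0.00635. Of 17 cholesterol synthesis genes, 0 had a positive and 8 a negative term that passed (0 and 15 adjusted over the list alone), with INSIG1 at -2.67 (SE 0.42), CYP51A1 at -2.49 (SE 0.47) and MSMO1 at -1.75 (SE 0.27). Of 34 unfolded protein response genes, 7 were negative (18 adjusted over the list alone), with CRELD2 at -1.40 (SE 0.23) and SYVN1 at -1.30 (SE 0.18). Camera called both lists (adjusted p = 7.91e-09 and 1.07e-08), and both had adjusted p = 0.762 with an estimated correlation. Of 19 epithelium markers, 3 were negative and 1 positive (9 and 1 adjusted over the list alone), with CLDN4 at -2.36 (SE 0.48) and CLDN10 at 2.44 (SE 0.52); camera called this list with adjusted p = 0.000337, and 0.818 with an estimated correlation. CLDN10 lost its call without 9 of the 12 arrays, with adjusted p from 0.0168 to 0.0956. Limma called 648 probe sets, 143 positive and 505 negative. The count was 316, 197 and 317 without control replicates 1, 2 and 3, 198, 167 and 190 without estrogen replicates 1, 2 and 3, 1140 and 391 without progesterone replicates 1 and 3, and 1112 and 309 without combined replicates 1 and 3.

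The estrogen and combined responses had the highest correlation of the hormone groups. Across probe sets, which are not independent replicates, the log2 changes against control correlated at 0.80 between the estrogen and combined groups, 0.26 between estrogen and progesterone, and 0.17 between progesterone and combined. Unchanged groups simulated against the same controls gave mean correlations of 0.462, 0.478 and 0.466 in 100 simulations, with 95% of values between -0.02 and 0.72, -0.06 and 0.83, and 0.0019 and 0.76. The value of 0.80 lay above its range and the others inside theirs, and the observed covariance exceeded the simulated one by 0.196, 0.0294 and 0.0119. In comparisons that shared no arrays, the estradiol benzoate change without and with progesterone correlated at 0.50, and the progesterone change without and with estradiol benzoate at -0.13, both inside the simulated ranges of -0.55 to 0.58 and -0.61 to 0.66. Their covariances differed from the simulated ones by 0.166 and -0.0175. Limma had called 2571 probe sets higher with estradiol benzoate alone. Of these, 2198 were also higher in the combined group than in the progesterone group, with 1234 called. Of 2450 called lower, 2201 were also lower there, with 1323 called. Both comparisons may join sampling day with estradiol benzoate. Among probe sets called in both the estrogen and the combined group, 1592 were higher in both (284 for independent lists) and 1840 lower in both (311), with 0 called in opposite directions. Progesterone and combined groups shared 96 higher (61.8 for independent lists) and 119 lower (28.2), and 71 of the 560 called higher with progesterone were called lower in the combined group. With 3 control arrays the controls could not be split into parts of 2 or more, so part of the excess may come from the shared controls. Of the 560 probe sets raised by progesterone, with a median of 1.02, 166 were higher in the combined group than in the estrogen group, and the median of that difference was -0.14. Of the 222 lowered by progesterone, with a median of -0.77, 120 were lower in the combined group than in the estrogen group. The median of their difference was -0.02. A called interaction against the progesterone change was found in 334 of the 560, but that term subtracts the progesterone difference by which they were chosen, so its sign is biased by the choice.

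**Figure D4:**
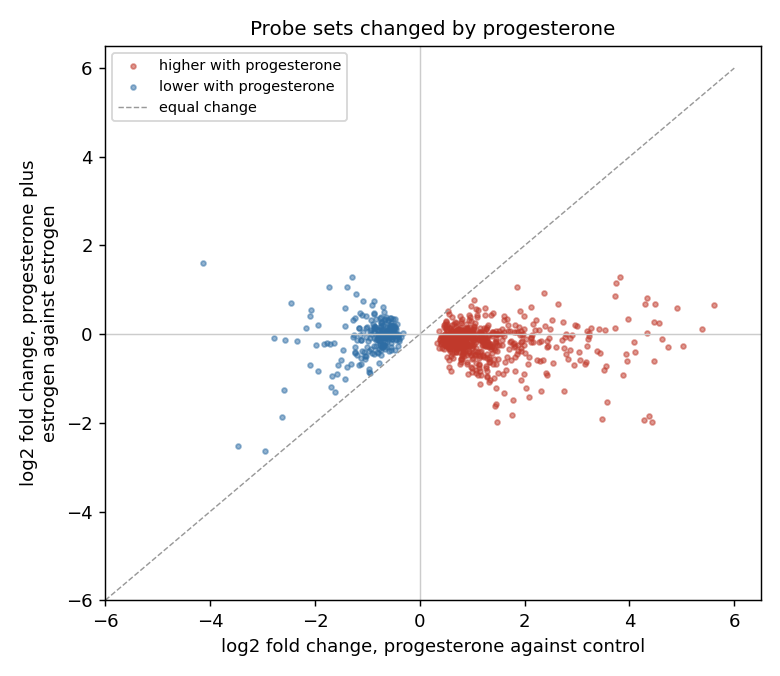
Each point is a probe set called in the progesterone group against control, with its log2 change there on the x axis and its log2 difference between the combined and estrogen groups on the y axis; the dashed line marks equal changes. The 560 probe sets raised by progesterone had a median of 1.02 on the x axis and -0.14 on the y axis.

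Of the hormone-related genes fixed for every comparison, the progesterone receptor PGR rose by 0.92 with estradiol benzoate (SE 0.21, n = 3 per group, adjusted p = 0.0113) and by 0.91 in the combined group (SE 0.21, 0.0117), while its value with progesterone was -0.40 (SE 0.21, 0.322). Without estrogen replicate 1 the estrogen value was 0.82 with adjusted p = 0.0501, in a range from 0.00227 to 0.0501 over the arrays left out. The estrogen receptor ESR2 rose by 1.01 with progesterone (SE 0.21, 0.0259). That call was lost without control replicates 2 and 3 (0.0763 and 0.0769) and progesterone replicates 2 and 3 (0.0690 and 0.0720), with 0.0124 as the lowest value. ESR2 had -0.06 with estradiol benzoate (0.877) and -0.20 in the combined group (0.501). The receptor ESR1 had 0.72 with estradiol benzoate (SE 0.62, adjusted p = 0.468), -0.74 with progesterone (0.563) and 0.48 in the combined group (0.595). The oxytocin receptor OXTR had -2.31 with progesterone (SE 0.73, 0.112), and 0.00141 without progesterone replicate 2, with 0.319 as the highest. It had 0.76 with estradiol benzoate (0.520) and -1.02 in the combined group (0.326), the latter with 0.0496 without progesterone replicate 2 and up to 0.598. It was lower with progesterone than with estradiol benzoate by -3.07 (SE 0.73, 0.0130). IGF1 rose by 0.49 with estradiol benzoate (SE 0.15, 0.0455) and by 0.56 in the combined group (SE 0.15, 0.0250), with 0.13 for progesterone (0.699). Those calls were lost without 7 and 4 of the 12 arrays, with adjusted p up to 0.163 without estrogen replicate 2 and 0.0808 without control replicate 3, from 0.0333 and 0.0140 as the lowest. FKBP5 had -0.02 with estradiol benzoate (SE 0.28, 0.965), 0.15 with progesterone (0.817) and 0.41 in the combined group (0.304; 0.0278 without progesterone replicate 2, in a range up to 0.460). LTF had 0.65 (SE 0.66, 0.543), -0.73 (0.593) and -0.85 (0.369) in the same order; without control replicate 3 its estrogen value was 1.64 with adjusted p = 0.00667, in a range up to 0.929. SERPINA14, a uterine serpin, had 0.54 with estradiol benzoate (SE 0.95, 0.744), 2.68 with progesterone (0.147) and 2.75 in the combined group (0.0585). Without combined replicate 3 the latter pair had adjusted p of 0.0390 and 0.00411, and without progesterone replicate 1 the combined value had 0.0454, in ranges up to 0.322 and 0.173.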

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

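The tests of tissue composition and of device timing, and the reading of the other splits of the arrays, were chosen only after the results were seen; both tests for a mislabelled array were written before their values were known.

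The interaction stood out because the change with estradiol benzoate differed with and without earlier progesterone. The devices were out by then, and sampling day and time after device removal may also enter the term. Limma called an interaction term in 648 probe sets. The genes named in any comparison with such a term were, on the negative side, BCAT1 (-6.41), BPIFB1 (-5.29), CYP39A1 (-5.07), PENK (-4.95), SLC39A2 (-4.73), CPN1 (-4.56), MEP1B (-4.31), SLC5A1 (-4.30), PTGS2 (-4.27), CRIPTO (-4.19), CHGA (-3.80), MGP (-3.06), MGAT5B (-1.52), GMPPB (-1.10) and HYOU1 (-0.85). On the positive side were SMPX (5.75), FBXO32 (3.93), GEM (2.78), FOXP2 (2.58), CLDN10 (2.44), ISLR (2.36), COL12A1 (2.04), TRAF5 (1.93), KCNJ8 (1.79), OLFML1 (1.78), CYP4B1 (1.74), TCP11L2 (1.39), CPNE5 (1.11), SPARCL1 (1.06) and ASF1B (0.60). FBXO32, GEM, CLDN10, ISLR, COL12A1, OLFML1 and CRIPTO lost their calls without 7, 10, 9, 10, 8, 8 and 7 of the 12 arrays, with adjusted p up to 0.0740, 0.0895, 0.0956, 0.125, 0.0884, 0.0964 and 0.111. Lists called by camera had median terms of -1.35 for cholesterol synthesis, -1.02 for epithelium, -0.41 for the unfolded protein response, -0.29 for heat shock proteins and -0.24 for oxidative phosphorylation, and of 1.05 for smooth muscle, 0.76 for mitosis, 0.58 for neutrophils, 0.48 for macrophages and dendritic cells, 0.31 for mammary secretory epithelium, 0.22 for DNA replication and 0.20 for ribosomal proteins. With an estimated correlation their adjusted p was 0.762 or 0.818. Several of these calls were lost without single arrays: the smooth muscle median was 0.42 (adjusted p = 0.309) without combined replicate 2, that of macrophages 0.18 (0.322) and of neutrophils 0.31 (0.0618) without control replicate 3, and that of DNA replication 0.11 (0.247) without combined replicate 1. Of the 12 arrays, 3, 6, 4 and 1 ended these calls in that order, 7 that of mammary epithelium (up to 0.109, without progesterone replicate 3) and 6 that of heat shock proteins (up to 0.182, without combined replicate 3). The lowest adjusted p over the arrays left out was 6.37e-05, 0.00149, 0.0116, 0.00404, 0.0186 and 0.000736 for these 6 lists.

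Of 100 splits of the 12 arrays, 2 gave as many interaction calls as the real 648, the real split among them, and 90 gave 0 calls by limma. The highest other count was 8515, from a split with the arrays given estradiol benzoate on 1 side, which points to a structure of the samples by that treatment. Nearly every other split mixed arrays with and without estradiol benzoate inside the groups, which widens the residuals, so these splits decide nothing about the interaction. For called lists 30 of the same splits gave as many as the real 12, and the highest other gave 17. For pairs of groups the 10 splits of 6 arrays are too few for a share under 0.05. The real count and the highest other count of probe sets were 5021 and 0 for estrogen against control, 782 and 5 for progesterone, 5702 and 0 for the combined group, 7173 and 0 for the combined group against progesterone, 5 and 2 against estrogen, and 5385 and 0 for progesterone against estrogen, with 1 split of 10 reaching the real count in each. For lists the real counts were 6, 6, 12, 9, 9 and 3 in that order, and the highest other counts were 13, 14, 16, 13, 14 and 10. As many or more came from 9, 10, 7, 8, 5 and 9 of the 10 splits, the real one among them. In every pair, some other split gave more lists called by camera with a preset correlation than the real one. Each other split kept more arrays of one group than of the other on a side, so part of the treatment difference remained. These list counts therefore cannot show how many lists would be called without a difference, and they decide nothing about the lists.

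The Affymetrix control probe sets, left out of the counts above, were tested because they had not been analysed with the rest. Of 112, limma called 10 in estrogen against control (9 higher and 1 lower), 13 in the combined group against control, 27 in the combined group against progesterone, 4 in the combined group against estrogen and 2 in the interaction, with 0 lower in each of these after the first. It called 11 in progesterone against estrogen, with 0 higher, and 0 in progesterone against control. The largest difference among them was 1.20 in size in the interaction and 1.07 in estrogen against control. Every set called against control had a name that begins with AFFX-Bt. The control sets named BioB, BioC, BioD and Cre were not called there, and their largest change was -0.14, for BioDn-3 with progesterone. Those named Dap, Lys, Phe and Thr were not called there either, but moved more. Their largest change was -0.458, for r2-Bs-thr-3 with progesterone, and r2-Bs-dap-M had 0.323 in the combined group. No cause was tested.

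The 560 probe sets raised by progesterone were not higher in the combined group than in the estrogen group, with a median difference of -0.14 (jackknife SE 0.07). Less epithelium in the combined samples, or muscle tissue in them, is a candidate explanation. With the epithelium level as covariate the median was -0.0154 and with the smooth muscle level -0.101, where a median of at least 0.511 was needed. Neither covariate brought the median to that value. Within groups these levels varied most among the combined arrays, and the epithelium list holds CLDN10, which fell with progesterone. The covariates therefore cannot part composition from treatment, and both explanations stay open. The covariates had first been tried on the interaction term, with the same outcome, and were moved because that term shares arrays with the choice of the 560. A longer time between device removal and sampling cannot be told apart from an effect of estradiol benzoate, since the design joins them, and the value of -0.140 could come from either. Injection on day 5 in the estrogen group and day 6 in the combined group may also enter this difference.

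Replicate 2 of the combined group had the highest value of all 12 arrays for 13 of 13 smooth muscle markers, among them DES (13.8) and MYH11 (13.5). A mislabelled control or progesterone sample is argued against, since 94.4% of 551 probe sets raised by estrogen lay above every control array in it, against 41.9% to 50.8% in progesterone arrays. Muscle tissue in this sample stays open, since these markers are the ones that set the array apart and lend that explanation no support of their own, and muscle and vessel markers are also expressed in endometrium.

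Replicate 1 of the combined group lay nearer to the estrogen arrays than the other combined arrays did. A mislabelled estrogen-only sample is a candidate explanation, but on a scale from the estrogen arrays (0) to the other combined arrays (1) it stood at 0.338 over 300 probe sets, while estrogen arrays left out in turn stood at 0.108, 0.0112 and 0.110. With 3 such arrays the comparison argues against that explanation only modestly. Why this array lay closer stays open.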

How the results depend on the processing

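The setting without both arrays of lowest weight was chosen only after the data were seen, and a different pseudocount was not run because the values are log2. In estrogen against control (5021 probe sets) array weights gave 7562, at least 2-fold 1052 and 1 probe set per gene 2569, and leaving out 1 array gave 3174 to 5443. In progesterone against control (782) only the arrays compared gave 324, 2-fold 358, 1 per gene 471, adjustment over all 7 comparisons 1712, and leaving out 1 array 303 to 1194. In the combined group against control (5702) these were 3768 for only the arrays compared, 1202 for 2-fold, 2768 for 1 per gene and 3709 to 6309 for 1 array left out. Against progesterone (7173) they were 2773, 1771 and 3279, with 4146 without both arrays of lowest weight. Against estrogen (5), quantile normalization and array medians subtracted gave 3 each, dim probe sets left out 12, array weights 15, both arrays of lowest weight left out 1, all 7 comparisons 888, and 1 array left out 0 to 320; the replicate block and only the arrays compared gave 0 each by limma, with 3404 and 3619 at an unadjusted p under 0.05. Progesterone against estrogen (5385) gave 1401 for 2-fold, 2666 for 1 per gene and 3396 to 5813 for 1 array left out. The interaction (648) gave 1075 with array weights, 311 with the replicate block, 428 for 2-fold, 1696 over all 7 comparisons and 167 to 1140 with 1 array left out. Adjustment over all 7 comparisons does not hold the 0.05 rate within a single comparison. Of 57 list calls, the estimated correlation left 0, and fry made 39 calls, with 35 list results weaker and 11 stronger. Of the results of named genes, 13 were weaker with the replicate block and 16 with only the arrays compared. Residuals of 18 pairs with the same replicate number correlated at a median of -0.0042, so the numbers did not pair the cows. The cause was not tested for any of these shifts, and no alternative reversed the direction of a called list or named gene. The larger of the higher and lower counts did change in some settings, as given above for the combined group against control and against progesterone. With 3 arrays per group, what small counts can show is limited.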

Other observations

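The genes in this part were chosen only after their values had been seen. They are single genes, with no count of comparable genes that did not change. With estradiol benzoate, the parathyroid hormone-related peptide PTHLH rose by 2.84 (SE 0.38, n = 3 per group, adjusted p = 0.000874 by limma), neurotensin (NTS) by 2.77 (SE 0.43), the secretogranin SCG2 by 2.59 (SE 0.50) and the natriuretic peptide NPPC by 2.13 (SE 0.24). Adrenomedullin (ADM) rose by 1.80 (SE 0.48) and galanin (GAL) by 1.26 (SE 0.38). In the combined group the values were 1.69, 1.87, 1.89, 1.61, 2.03 and 1.49 for PTHLH, NTS, SCG2, NPPC, ADM and GAL. With estradiol benzoate alone, the endothelin genes EDN3 and EDN1 had -1.72 (SE 0.28) and -1.04 (SE 0.23). Neuromedin B (NMB) rose with progesterone by 2.63 (SE 0.62, adjusted p = 0.0466 by limma).

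HSD11B1, which regenerates active glucocorticoid, rose with estradiol benzoate by 2.94 (SE 0.53, adjusted p = 0.00352 by limma), while HSD17B6 fell by 2.12 (SE 0.58) and HSD17B11 by 1.14 (SE 0.16). The retinaldehyde dehydrogenase ALDH1A1 fell by 1.94 (SE 0.30). The retinoic acid binding protein CRABP2 rose by 1.79 (SE 0.40) and the retinol receptor STRA6 by 1.38 (SE 0.42); STRA6 had 0.71 in the combined group with adjusted p = 0.242. AKR1C4 fell by 2.35 with estradiol benzoate (SE 0.35), rose by 2.37 with progesterone (SE 0.35) and fell by 1.42 in the combined group (SE 0.35). AKR1C4 had 6 probe sets, and NPPC and STRA6 had 2 each. Only the one of highest mean was read for these genes.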
